A study of Homo sapiens with 6 samples.

How the data were processed

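Polyadenylated RNA was sequenced from H9 cells, an established human T lymphoma cell line that the labels describe as cutaneous. Per the labels, 3 libraries came from cells given the vehicle DMSO (control) and 3 from cells given PA4 at 1 µM for 24 h. PA4 is the code name of the compound under test. RNA was isolated with the Direct-zol kit and libraries were made with the Kapa mRNA HyperPrep kit, per the labels' protocols. The labels do not say that the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

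The deposited table held raw counts of reads per gene for 26485 gene symbols, with 1 column per library, no normalization and no pooling. It also held the length in bases of each gene model as the authors' counting tool writes it, which was used only to compare fold changes with gene length. Per the submitters' processing notes, the tools were Trimmomatic 0.39 and fastp 0.23.2, which trim reads, the aligner STAR 2.7.9a, and featureCounts of Subread 1.6.4, and the genome build was hg38, which is GRCh38. The gene annotation, the strand setting, the handling of reads with several alignments and other parameters are not given in the sources used here. Whether reads of overlapping genes on opposite strands were told apart in counting is therefore not known. Of the 28 genes called below, 7 shared exon bases with another tested gene in GENCODE release 29, and the share was at most 2.85% of exon bases except in TMEM97, at 11.9% with IFT20, and in ACAT2, at 34.8% with SOD2 and 12.5% with TCP1. Coordinates of named genes were taken from the RefSeq gene table of GRCh38.

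Library totals were 19260434, 19210122 and 19033853 counts for control replicates 1 to 3 and 20251875, 22875191 and 18282212 counts for PA4 replicates 1 to 3, with 15023 to 15278 genes having at least 1 count. The 10 most abundant genes took 4.57% to 4.74% of a library's counts. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 1.48 to 6.81 over genes with 20 or more counts in the pair, so no pair was treated as copies of 1 library. Repeat libraries of 1 culture can also differ in this way. The common biological coefficient of variation was 3.92%, and the median standard error of a log2 fold change was 0.069 over the tested genes.

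Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, which left 12107 genes holding at least 99.9% of each library's counts. Scaling used TMM factors, all within 0.33% of 1. Dispersions were estimated with estimateDisp, and PA4 was compared with control by glmQLFit and glmQLFTest, two-sided, with no covariate and all 6 libraries in the fit. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes given below come from this edgeR test unless another tool is named. CPM are counts divided by the TMM-scaled library size, and errors of log2 fold changes are standard errors derived from the F statistic, with 95% intervals from its degrees of freedom. In all text, log2 fold changes are PA4 against control.

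The comparison, the tests, 31 gene lists, 6 lists of markers of other cell types and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes with a mean CPM of 10 or more and no overlap between the groups, leaving out clone, LOC, pseudogene-like and antisense names. It added up to 3 called members of each list in its main direction and up to 1 in the other, with a mean CPM of 5 or more, and MYC, CAMK2G, CAMK2D, DDIT3, ATF4, SQSTM1, HMGCS1, CDKN1A and CCNB1 whatever their values. List members and called genes whose changes are named outside the rule are said to be so. Genes named for overlapping exons, cell identity or differences between libraries, such as ACAT2, EPCAM, NCR3, RN7SL1, RN7SL2 and RNA28S5, also lie outside it and were chosen after their values were seen, and the results of some single genes are not reported here. Of 818 list entries, 751 matched a symbol of the table, 50 matched through an older name, and 17 did not match, among them the mitochondrially encoded genes and the T cell receptor constant genes. Lists with 5 or more tested members, 29 in all, were tested with camera at its preset inter-gene correlation of 0.01, adjusted over those lists. Camera with an estimated correlation and fry stand beside it.

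The procedure was tested on 10 simulated data sets drawn from the means, sizes and dispersions of these libraries, each with 12107 genes of which 200 were changed. For this comparison it recovered 64.2% of genes changed 1.25-fold, 83.4% of those changed 1.5-fold, 95.0% of those changed 2-fold and 97.4% of those changed 4-fold. The simulated sets held more changed genes than the 28 called in these data. That eases the adjusted threshold, so these shares may overstate the recovery of small changes here. Unchanged genes made up 6.66% of the procedure's calls, 3.65% to 10.3% in single simulations. The number of simulations was raised to 10 after the first had given 10.3%. A list of 24 genes shifted by 0.3 log2 was called in each of the 10 simulations, and 0 of 300 lists of unchanged genes were called by camera, although simulated genes were independent of one another, unlike real ones.

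Alternatives were DESeq2 size factors, upper-quartile factors, library size alone, no low-count filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, voom of limma 3.58.1, the replicate number as a covariate, and each library left out in turn. After the data had been seen, the following were added: offsets that remove each library's trend with transcript GC content (lowess, span 0.3, GC content from GENCODE release 29 for 97.7% of tested genes and each called gene), the same offsets with the replicate number as a covariate, counts thinned to the smallest library, and lists without the called genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.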

Results

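Gene expression was measured by RNA sequencing in 6 libraries of H9 cells, 3 from cells given vehicle and 3 from cells given 1 µM PA4 for 24 h. Library totals ranged from 18282212 to 22875191 counts. Transcripts of T cells were abundant, with 2099 to 2529 counts of CD3E and 1808 to 2280 counts of the skin-homing receptor CCR4 per library, whereas CD4 had 6 to 12 counts and CD2 at most 1. Markers in the 6 lists of other cell types were mostly near 0. Median counts per library were 1.0 in control and 1.33 with PA4 for B cells. They were 0.667 and 0.5 for natural killer cells, and 1.5 and 2.67 for epithelial cells. The medians were 0 in both groups for myeloid cells, fibroblasts and pluripotent stem cells. The most abundant of these markers were EPCAM, at a mean of 2574 counts, and NCR3, at a mean of 521 counts. In edgeR 0 markers of the 6 lists were called, against 2 at an unadjusted p under 0.05. Outside the lists, LIN28B had 3693 to 4860 counts per library and the keratin gene KRT7 had 1133 to 1679, both named after their values were seen.

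The comparison asked how the expression profile of H9 cells differed after a treatment that the submitters describe as causing cell death. Genes of sterol synthesis and uptake rose with PA4. HMGCS1, which makes the HMG-CoA that feeds the mevalonate pathway, rose most, from 345 ± 17.5 CPM (SD, n = 3) in control to 669.9 ± 2.02 CPM (SD, n = 3) with PA4, or 1.94-fold. INSIG1, a sterol-regulated brake on sterol synthesis, rose 1.64-fold, and MSMO1, an enzyme of a later step, rose 1.65-fold. The fatty acid desaturases FADS2 and FADS1 rose 1.43-fold and 1.33-fold. The genes that fell were ABCG1, a cholesterol exporter, to 0.744 of its control level, and PAQR8, a membrane progestin receptor, to 0.804 of its control level.

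In edgeR's quasi-likelihood test 28 of 12107 genes were called, 26 higher and 2 lower with PA4, and 20 of them belonged to the sterol or fatty acid list. Over all tested genes, the 3 PA4 libraries lay beyond the 3 control libraries in 11.2%, where chance gives 10%. There were 0 called genes with a change of 2-fold or more by edgeR, DESeq2 or limma-voom, and at an unadjusted p under 0.05 edgeR gave 3 such genes higher and 4 lower. At that unadjusted p, 326 genes were higher and 315 lower, 641 in all, where chance gives 605. For 99.8% of the 8564 genes with a mean of 10 CPM or more, the 95% interval of the fold change lay within 1.5-fold in both directions. DESeq2 called 40 genes and limma-voom 27, with 28 and 27 of the 28 among them. The count was 74 without control replicate 1, 17 without control replicate 2 and 18 without PA4 replicate 1, and it was 106 with offsets for GC content, which were chosen after the data were seen. Of the 28 genes, 17 were called in each of 17 alternative settings, and these were 15 sterol or fatty acid genes together with TSC22D3 and PAQR8. In fits that leave out 1 library, the edgeR adjusted p of TSC22D3 reached 0.0498, close to the threshold, and that of PAQR8 0.0281.

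**Figure D1:**
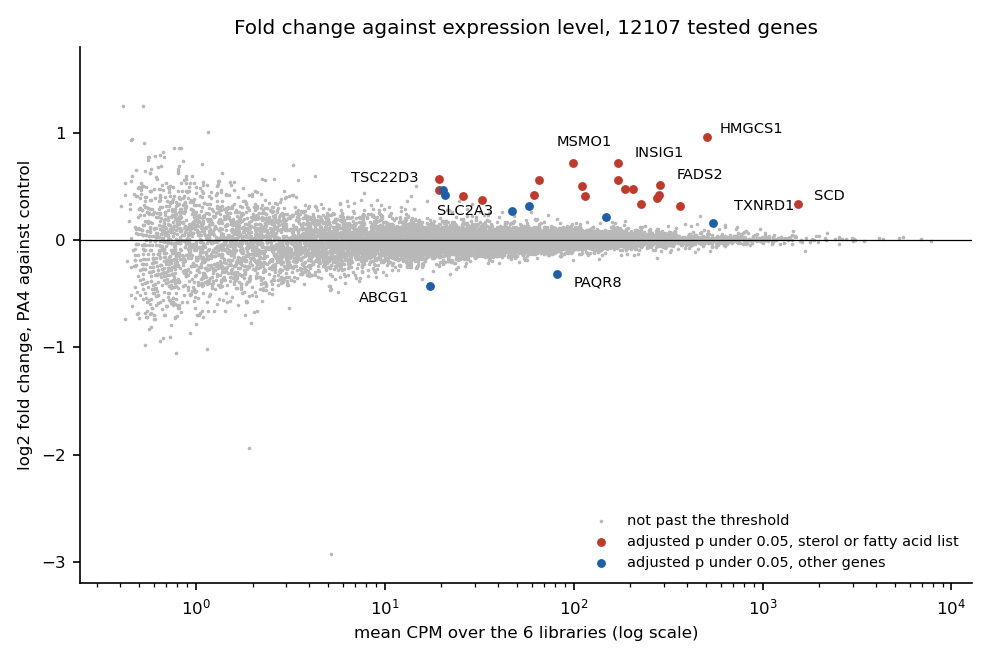
Log2 fold change of each tested gene, PA4 against control, plotted against its mean CPM over the 6 libraries on a log scale, with the 28 called genes in colour. The called genes lie between a rise of 1.94-fold (HMGCS1) and a fall to 0.744 of the control level (ABCG1), and 20 of them belong to the sterol or fatty acid list.

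Within the list of sterol synthesis and uptake, 16 of 24 tested members rose, 0 fell and 8 were not called, and 23 passed when adjusted over the list alone. At an unadjusted p under 0.05, 23 were higher and 0 lower, DESeq2 called 19 and limma-voom 16. Calls covered the pathway from its first steps to its last. MVK, MVD and IDI1, which turn mevalonate into isoprenoid units, rose by 0.47 ± 0.09, 0.57 ± 0.10 and 0.50 ± 0.05 log2 (SE), and SQLE and CYP51A1, which act in sterol ring formation and processing, both rose by 0.48 ± 0.04 log2 (SE). MSMO1, a demethylation enzyme, rose from 75.1 ± 0.813 CPM (SD, n = 3) to 123.6 ± 2.41 CPM (SD, n = 3), with an adjusted p of 2.63e-08, and the adjusted p of HMGCS1 was 8.62e-11. The 24 members all had positive log2 fold changes, with a median of 0.42, and camera gave an adjusted p of 2.09e-242, or 0.000273 with an estimated correlation. In the fit with the fewest calls, that without control replicate 2, 12 members were called. The calls of MVK and HSD17B7 were lost without control replicate 2, PA4 replicate 1 or PA4 replicate 3, that of MVD without control replicate 2, PA4 replicate 1 or PA4 replicate 2, and that of DHCR7 without control replicate 2, with adjusted p-values of at most 0.258, 0.213, 0.152 and 0.0844 in that order. HSD17B7 and DHCR7 were named after their values were seen, and reads of HSD17B7 can be shared with its pseudogene HSD17B7P2.

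Of 15 tested genes of fatty acid synthesis, 4 rose, 0 fell and 11 were not called, while 8 passed when adjusted over the list alone, 8 were higher and 0 lower at an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 4. FADS2 rose from 236 ± 19.98 to 337 ± 8.85 CPM (SD, n = 3 each), with an adjusted p of 1.02e-05. FADS1 lies beside it on chromosome 11 of GRCh38, at 61799627 to 61817003 against 61816203 to 61867354 for FADS2, and the genes shared 142 exon bases, 1.8% of those of FADS1. ELOVL6, a fatty acid elongase, rose by 0.38 ± 0.07 log2 (SE), a call lost without control replicate 2 or any 1 of the PA4 replicates, with an adjusted p of at most 0.249. SCD, the stearoyl-CoA desaturase, named after its values were seen, was the most abundant called gene and rose from 1360.4 ± 0.691 to 1714 ± 13.4 CPM (SD, n = 3 each). The list's median log2 fold change was 0.10, with a camera adjusted p of 2.13e-31, or 0.00319 with an estimated correlation. SREBF1, at -0.056 ± 0.065 log2 (SE), and FASN, at 0.22 ± 0.05 log2 (SE) and an adjusted p of 0.173, were among the members not called, and both were named after their values were seen.

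**Figure D2:**
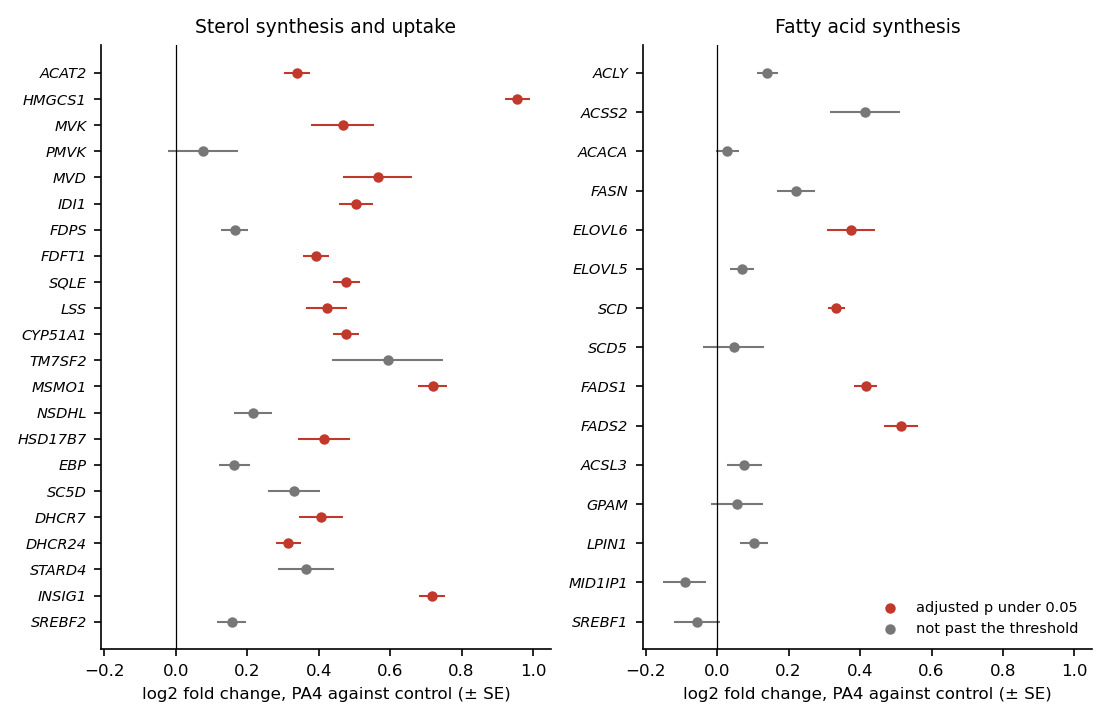
Log2 fold change with its standard error, PA4 against control in 3 libraries each, for genes of sterol synthesis and uptake in approximate pathway order (left) and the 15 tested genes of fatty acid synthesis (right), with called genes in red. The sterol genes drawn all lie to the right of 0, and 4 of the fatty acid genes are called.

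Outside these lists 8 genes were called. TSC22D3, a gene known to respond to glucocorticoids, rose from 17.05 ± 0.765 to 23.5 ± 0.621 CPM (SD, n = 3 each), or by 0.46 ± 0.07 log2 (SE), with an adjusted p of 0.00497. The growth factor gene VEGFA, from the hypoxia list, rose 1.249-fold, the glucose transporter gene SLC2A3, from the glycolysis list, rose 1.21-fold, and TXNRD1, a thioredoxin reductase from the list of NRF2 targets, rose 1.12-fold. LMNA and TMEM97, named after their values were seen, rose 1.34-fold and 1.16-fold. LMNA encodes nuclear lamins A and C, and TMEM97 the sigma-2 receptor, a protein of sterol transport. PAQR8, on chromosome 6 of GRCh38 at 52362151 to 52407777, fell from 90.9 ± 1.84 to 73.1 ± 1.14 CPM (SD, n = 3 each), with an adjusted p of 0.00138. ABCG1, on chromosome 21 at 42199689 to 42297244, fell from 19.9 ± 1.38 to 14.8 ± 0.96 CPM (SD, n = 3 each), with an adjusted p of 0.0404. The calls of ABCG1, SLC2A3, TMEM97 and TXNRD1 were lost without control replicate 2 or any 1 of the PA4 replicates, that of VEGFA without control replicate 2, PA4 replicate 1 or PA4 replicate 3, and that of LMNA without control replicate 2, control replicate 3, PA4 replicate 1 or PA4 replicate 2, with adjusted p-values of at most 0.388, 0.427, 0.472, 0.376, 0.249 and 0.412 in that order. Over all 6 fits that leave out a library, the lowest adjusted p of each gene, from a fit that kept its call, lay between 0.00505 and 0.0161. Those of SLC2A3 and LMNA were also lost with library size alone, at adjusted p-values of 0.0635 and 0.0539, that of SLC2A3 with limma-voom, at 0.0501, and that of LMNA with counts thinned to equal depth, at 0.0718.

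**Figure D3:**
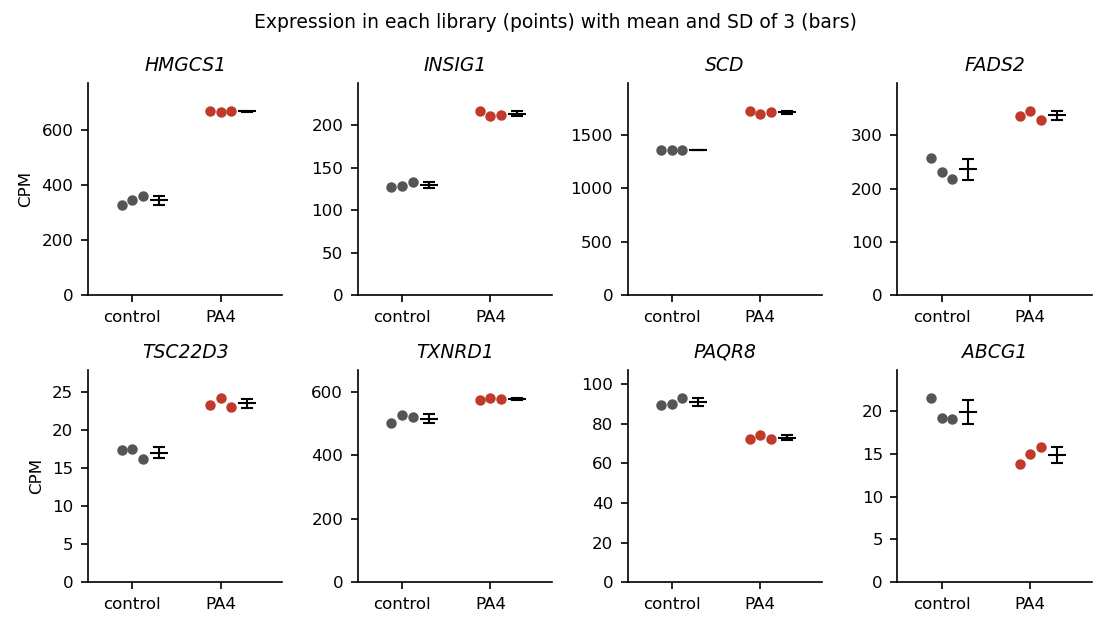
CPM of 8 called genes in each of the 3 control and 3 PA4 libraries (points), with the mean and SD of each group (bars) and axes from 0. The groups do not overlap in any of the 8, from HMGCS1 at 345 and 669.9 CPM to ABCG1 at 19.9 and 14.8 CPM.

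The list of the integrated stress response, the program of ATF4 and CHOP, was called upward by camera at its preset correlation, but neither with an estimated correlation (adjusted p = 0.193) nor by fry (adjusted p = 0.0961). Of 32 tested, 0 were called by edgeR, DESeq2 or limma-voom, 10 were higher and 0 lower at an unadjusted p under 0.05, and 4 passed when adjusted over the list alone. These were the cystine transporter gene SLC7A11, at 0.37 ± 0.09 log2 (SE), TRIB3, at 0.23 ± 0.07, the tryptophanyl-tRNA synthetase gene WARS, at 0.12 ± 0.03, and the asparagine synthetase gene ASNS, at 0.11 ± 0.04, named after their values were seen. The list's median was 0.079 log2, with positive values in 26 of 32 members, and camera gave an adjusted p of 3.22e-08, in a range of 1.44e-10 to 0.193 over the alternatives. DDIT3, the gene of CHOP, was at 0.10 ± 0.13 log2 (SE) and ATF4 at -0.015 ± 0.034 log2 (SE), neither of them called.

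Of 23 tested NRF2 targets, which act against oxidative stress, TXNRD1 alone was called by edgeR and limma-voom, 2 passed when adjusted over the list alone and 2 were called by DESeq2. The second of these was FTH1, the ferritin heavy chain, at 0.15 ± 0.03 log2 (SE), named after its values were seen. The list's median was 0.055 log2, and camera's adjusted p of 6.83e-05 became an adjusted p of 0.267 with an estimated correlation, and 0.147 by fry, in a range of 2.2e-06 to 0.267 over the alternatives. At an unadjusted p under 0.05, 4 members were higher and 0 lower. The list of cutaneous T lymphoma markers had the only downward call, with a median of -0.078 log2 over 14 tested genes and a camera adjusted p of 0.0333, which became an adjusted p of 0.267 with an estimated correlation. Among its members 0 were called by edgeR and limma-voom and 1 by DESeq2, 3 were lower and 0 higher at an unadjusted p under 0.05, and the 1 that passed when adjusted over the list alone was TOX, a regulator of T cell development, at -0.18 ± 0.04 log2 (SE), named after its values were seen. That list's call was lost without control replicate 1, control replicate 2, PA4 replicate 1 or PA4 replicate 3, with camera adjusted p-values of 0.134, 0.0664, 0.114 and 0.0507, and with no low-count filter, at 0.138, and by fry, at 0.0961, in a range of 0.0156 to 0.267 over the alternatives.

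**Figure D4:**
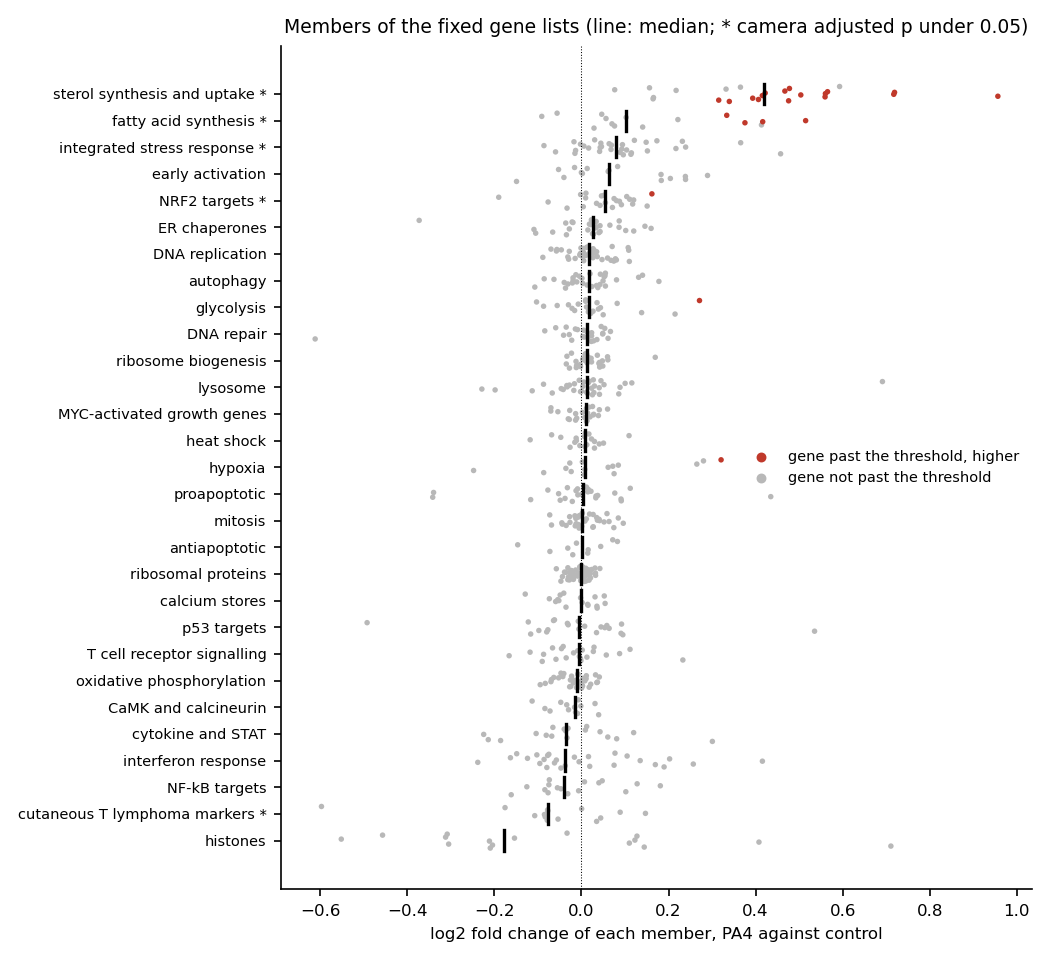
Log2 fold change, PA4 against control, of each tested member of the 29 lists tested (points, called genes in red), with each list's median as a line and an asterisk at lists with a camera adjusted p under 0.05. The sterol list stands at a median of 0.42 and the fatty acid list at 0.10, and the histone list, at -0.18, holds mostly genes of about 1 CPM and was not called.

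The other 24 lists tested were not called, with camera adjusted p-values of 0.0746 to 0.868. In lists of cell division and DNA upkeep, 0 of 139 genes were called by edgeR, DESeq2 or limma-voom, against 3 at an unadjusted p under 0.05, and the median log2 fold changes were 0.016 for DNA replication, 0.0021 for mitosis, 0.013 for DNA repair, -0.0066 for p53 targets and -0.18 for histones. In lists of cell death, 0 of 36 genes were called by these tools, against 4 at an unadjusted p under 0.05, with medians of 0.0030 for proapoptotic and 0.0015 for antiapoptotic genes. The interval of 32 of these 36 genes lay within 1.5-fold. The proapoptotic gene BMF, the 1 gene of these lists that passed when adjusted over its list alone, was at 0.43 ± 0.10 log2 (SE) with an adjusted p of 0.1425, and was named after its values were seen.

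Endoplasmic reticulum chaperones and heat shock genes, with medians of 0.025 and 0.0077, had 0 called genes of 48 by the same tools and 4 at an unadjusted p under 0.05. Lysosome and autophagy genes, with medians of 0.012 and 0.016, had 0 of 65 and 5. Lists of growth and energy metabolism had 0 of 150 called and 0 at an unadjusted p under 0.05, with medians of 0.012 for MYC-activated growth genes, 0.012 for ribosome biogenesis, -0.0016 for ribosomal proteins and -0.0098 for oxidative phosphorylation, and the interval of each of the 150 genes lay within 1.5-fold. Glycolysis and hypoxia genes had medians of 0.016 and 0.0077, with SLC2A3 and VEGFA the 2 called of 37. In each of these lists 1 more gene passed when adjusted over the list alone, ALDOC at 0.22 ± 0.06 log2 (SE) and NDRG1 at 0.26 ± 0.07 log2 (SE), both named after their values were seen.

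Lists of T cell function had 0 called genes of 99 by edgeR, DESeq2 or limma-voom, with 6 higher and 6 lower at an unadjusted p under 0.05. Their medians were -0.0067 for T cell receptor signalling, 0.062 for early activation, -0.039 for NF-kB targets, -0.037 for interferon response and -0.035 for cytokine and STAT genes. Calcium lists had 0 of 30 called by these tools and 1 at an unadjusted p under 0.05, with medians of -0.016 for calmodulin kinases and calcineurin and -0.0020 for calcium stores. The 4 tested metallothionein genes, too few for a list test, had a median of -0.049, with 0 called and 1 at an unadjusted p under 0.05, and the list of mitochondrially encoded genes was not analysed here because its members matched no symbol of the table. Means and medians differed in sign for DNA repair, proapoptotic, antiapoptotic and interferon genes, whose means were -0.016, -0.0045, -0.0053 and 0.0091, and camera's direction was that of the median except for antiapoptotic genes, where it was that of the mean. Over these lists together, edgeR gave 36 genes of 602 at an unadjusted p under 0.05, where chance gives 30. By group of lists, T cell function gave 12 where chance gives 5, and glycolysis and hypoxia 6 where chance gives 2. Growth and energy lists gave 0 where chance gives 8, and lists of cell division and DNA upkeep 3 where chance gives 7.

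Among the genes named whatever their values, MYC stood at 744 ± 26.7 CPM in control and 758 ± 17.8 CPM with PA4 (SD, n = 3 each), a log2 fold change of 0.028 with a 95% interval of -0.040 to 0.096. The calmodulin kinase genes CAMK2G and CAMK2D were at -0.084 ± 0.058 and -0.030 ± 0.042 log2 (SE), the cyclin gene CCNB1 at -0.0069 ± 0.038, and the autophagy receptor gene SQSTM1 at 0.13 ± 0.06. CDKN1A, the p21 gene, had 0.764 CPM in control and 1.11 CPM with PA4, and the interval of its log2 fold change was -0.0042 to 1.075. None of these 6 genes was called, with adjusted p-values of 0.920 to 0.997.

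Libraries differed within the control group as well. Across genes, the log2 ratio of control replicate 1 to control replicate 3 followed transcript GC content with a Spearman rho of 0.712, and genes are not independent replicates. Control replicate 3 held 450 counts of the signal recognition particle RNA RN7SL2 against 23 to 37 in the other libraries, and 74 counts of RNA28S5 against 310 to 563. Without that library 37 genes were called, 27 of the 28 among them.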

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

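Tests with GC-corrected offsets, with thinned counts and with called genes left out of the lists were chosen after the data were seen. Against 26 genes higher and 2 lower with PA4, no low-count filter gave 53 and 9, the replicate block 50 and 9, GC-corrected offsets 86 and 20, both together 91 and 24, and DESeq2's Wald test 36 and 4. Leaving out 1 library gave 16 to 50 higher and 1 to 24 lower. With 0 genes at least 2-fold lower in the reported fit, no low-count filter and the block gave 2 each, GC-corrected offsets 1, both together 2, and leaving out 1 library 0 to 2. RN7SL1 and RN7SL2, set apart by control replicate 3, were among the genes gained without the filter and with the block. The count at least 2-fold higher was 0 in each setting with a gene test. Of 4 lists higher and 1 lower, a correlation estimated per list and fry each gave 2 and 0, no low-count filter gave 6 and 0, and leaving out 1 library gave 4 to 7 and 0 to 2. Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at 0.025, -0.0084 and 0.13. Replicates 1 and 2 correlated better with another number, at up to 0.12 and 0.0083, but replicate 3 did not, at -0.032 or below. So few correlations cannot decide the question of pairing. Other scalings, the stricter filter, limma-voom and thinning left these counts within 1.5 times. Of 612 values of single named genes under the alternatives, 571 kept their side of the threshold, 41 of called genes lost it and 0 reversed, while 6 values of genes not called changed sign. The 612 include genes fixed in advance and not called in the reported fit, at adjusted p-values of 0.920 or more in edgeR. The cause of the changes was not tested.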

Other observations

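The tests with GC-corrected offsets as a setting, the test of the spread among the control libraries, the test of lists without some members at an estimated correlation and the test of LXR targets were chosen only after the results were seen.

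With offsets that remove each library's trend with GC content, 106 genes were called, 86 higher and 20 lower with PA4, all 28 reported genes among them, and the common biological coefficient of variation fell from 3.92% to 2.16%. The sterol list then had 23 of 24 tested members called and the fatty acid list 7 of 15, among them FASN, at 1.19-fold, and ACLY, at 1.10-fold. Of the integrated stress response list, 6 members were called, all higher: SLC7A5, TRIB3, WARS, SLC7A11, ATF5 and SLC1A5, from 1.30-fold for SLC7A11 to 1.08-fold for SLC1A5. Camera with an estimated correlation then gave that list an adjusted p of 0.0447, against 0.193 without the offsets, while the NRF2 list stood at 0.286 and the cutaneous T lymphoma marker list at 0.279 in that test. Among genes with lower levels were TOX, at 0.886 of control, IKZF1, a lymphoid transcription factor, at 0.904, and the cytokine receptor gene CSF2RB, at 0.881. The genes named for this fit were chosen after their values were seen. BMF, a proapoptotic gene, was at 1.35-fold, with 1 of 26 genes of its list called. In the same fit the highest of the other 9 splits of the libraries gave 6 genes.

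Per library, the median log2 level of the sterol list over the control mean was -0.039 to 0.025 in control and 0.3985 to 0.449 with PA4. The list's median log2 fold change was 0.4211 with the GC-corrected offsets and 0.4187 without them, which argues against a GC trend as its cause. The real split gave 28 called genes and the highest other split 6, and 0 and 0 genes at least 2-fold changed, while the 10 splits of 6 libraries are too few for a share under 0.05. An effect of PA4 stays open, and no mechanism for it was tested. Whether the replicates were separate cultures, and with it a difference between culture batches, stays open.

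ABCG1 is also a target of the LXR receptors, which respond to oxidised sterols, so its fall may reflect lower LXR activity. The 6 other LXR targets tested had a median log2 fold change of -0.016 and a camera p of 0.5511, but they went both ways, so this hypothesis stays open. In edgeR, MYLIP was at -0.19 ± 0.07 log2 (SE), with an adjusted p of 0.749, and PLTP, with a mean of 0.644 CPM, at 0.79 ± 0.32 log2 (SE), with an adjusted p of 0.876, both named after their values were seen.

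The rises of the integrated stress response and NRF2 lists are small, and a GC trend or a few members alone were weighed as causes. With the GC-corrected offsets their medians were 0.0794 and 0.0557 log2, against 0.0788 and 0.0550 without. These medians argue against a GC trend as the cause of either rise. Leaving out the 3 members of smallest p left camera p-values of 1.73e-06 and 0.00657 at the preset correlation of 0.01, but 0.0368 and 0.164, not adjusted, at the estimated correlations of 0.0744 and 0.107, so a few members alone stay open for the NRF2 list and are argued against only weakly for the other. With 5 lists called in the real split and 6 in the highest other split, and 10 splits too few for a share under 0.05, the calls at the preset correlation stay open, as genes that vary together across libraries could also give them. With a correlation estimated per list, adjusted p-values were 0.193 and 0.267. Per library, the stress response list's median log2 level over the control mean was -0.037 to 0.040 in control and 0.052 to 0.097 with PA4. For the NRF2 list it was -0.036 to 0.024 in control and 0.032 to 0.077 with PA4. In both lists the spread among control libraries was about as large as the rise.

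The spread among control libraries may come from GC content bias, since the log2 ratio of control replicate 1 to control replicate 3 followed GC content across genes with a Spearman rho of 0.7118. The same coefficient per library, against the mean of the 6, was 0.658 for control replicate 1, -0.109 for control replicate 2 and -0.577 for control replicate 3, and 0.123, 0.257 and -0.369 for PA4 replicates 1 to 3. The trends ran both ways within each group, and across genes the log2 fold change of PA4 against control had a rho of -0.051 with GC content and 0.083 with gene length. Whether library preparation or RNA quality gave rise to these trends was not tested.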
